A study of Homo sapiens with 22 samples.

How the data were processed

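Kasumi-1 is an established human acute myeloid leukaemia cell line that carries a fusion of RUNX1 and RUNX1T1. Per the labels' protocols, a lentivirus delivered either a control shRNA or an shRNA against FIP1L1, and cells that had taken it up were selected with puromycin. The labels name 2 FIP1L1 shRNAs, called shRNA 1 and shRNA 2 here. Both assays are given as total RNA extracted with Trizol. RNA-seq libraries were made with a kit (NEBNext Ultra) that, as its name is given, does not mark strand. The other assay was 3'READS, which sequences the 3' ends of polyadenylated RNA and so counts reads at each poly(A) site. The 22 samples were 12 RNA-seq libraries, 4 per group, and 10 3'READS libraries, with 3 for the control, 4 for shRNA 1 and 3 for shRNA 2. The labels call the replicates biological and do not say whether they came from separate transductions, so p-values measure the spread between these samples.

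The RNA-seq values were whole-number counts of reads per Ensembl gene, not normalised, as the authors deposited them. The 3'READS values were whole-number counts of reads per poly(A) site, given by chromosome, strand and position without gene names, as the authors deposited them. Per the submitters' processing notes, cutadapt 2.6, STAR 2.7.3a, DESeq2 and the build hg19 were used, each named without its role. The counting tool, the annotation, the strand setting of the counting and the distance used to join reads into sites are not given in the sources used here. Positions on chromosome 1 of the 3'READS table ran to 249233248, past the end of that chromosome in GRCh38, so 3'READS positions are given as hg19. Whether they count from 0 or 1 is not given in the sources used here. RNA-seq totals ran from 12236937 to 20388437 counts per library and 3'READS totals from 5666102 to 10846661. Counts of molecular identifiers were not used here, so precision from depth covers counting error only. No column of either table was left unassigned to a sample.

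Gene symbols came from GENCODE 29 on GRCh38 and a table of current symbols matched by Ensembl ID, and gene positions are GRCh38. Of 48162 IDs, 45342 had a symbol and 2820 did not. IDs without a symbol held 0.76% to 0.87% of reads per library and stayed in the tests. Without a stated strand setting, reads of a gene and of a gene on the other strand over the same bases cannot be told apart, which concerns 37 of the 83 genes named by rule. Members of the ribosomal protein, histone, HLA class II and CEACAM families share reads with close copies or pseudogenes, and their values are uncertain to that extent. An annotation of hg19 was not used here, so poly(A) sites were not assigned to genes.

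RNA-seq counts were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3. All 12 libraries stood in 1 fit with a term per group and 9 residual degrees of freedom. Scaling was TMM, low genes were removed with filterByExpr, the spread was estimated robustly, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. After the filter, 15834 genes were tested. CPM are relative to the TMM-scaled library size, given as mean ± SD over libraries. Fold changes are log2, with standard errors from the fit. Each shRNA was set against the control and shRNA 2 was set against shRNA 1. All tests were two-sided. The comparisons with the control share its libraries, so overlaps and correlations between them stand beside independent lists and fits with the controls split 2 and 2. They also stand beside 20 simulations in which no group was changed and both comparisons shared a simulated control. In 3'READS there were 10 such simulations, and 3 control libraries leave no split with 2 on each side.

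Gene lists were written from memory before the data were examined, and so were the groups, the tests, their thresholds and the rule for named genes. The 21 lists were cleavage and polyadenylation machinery, monocyte and macrophage, granulocyte, stem and progenitor, erythroid and megakaryocyte, lymphoid, MHC class II, mTORC1 signalling, mTOR pathway components, cholesterol biosynthesis, glycolysis, ATF4 and amino acid stress, cell cycle, p53 targets, interferon-stimulated, NF-kB and inflammatory, immediate early, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded and replication-dependent histones. For 18 list members no ID of the table was matched. Lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other genes, and adjusted over the 21 lists of a comparison. Camera with an estimated correlation and fry were alternatives.

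The rule for named genes took FIP1L1 in every library, and from genes called with both shRNAs in the same direction the 10 highest and the 10 lowest. These were ranked by the smaller absolute log2 change and needed every library of both shRNAs beyond every control library and a mean of at least 5 CPM. From each list it took up to 2 members with the largest rise and 2 with the largest fall that passed with both shRNAs, and every such member of the cleavage and polyadenylation machinery. It also took the 5 genes with the smallest adjusted p between the shRNAs, and up to 6 site pairs in each direction that passed with both shRNAs and held at least 100 reads.

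The 3'READS plan had to be changed, because it needed sites assigned to genes. Gene totals were replaced by tests of single sites, and shifts within 3' UTRs by shifts within pairs of neighbouring sites. Sites of intronic polyadenylation, a comparison of RNA-seq with 3'READS by gene, FIP1L1 itself in 3'READS and lists of genes with shifted sites were not analysed here. Of 1618880 sites, 60327 on nuclear chromosomes held at least 2 reads per library on average, and joining sites under 25 nt apart changed nothing. Of these, 28075 passed filterByExpr and were tested as the genes were. For pairs, sites of 1 strand were joined into runs wherever the next lay within 2000 nt, a distance set after the table had been seen and before any pair was fitted. The 2 sites of a run with most reads formed its pair if each held at least 5% of the reads of the run and both together at least 20 reads per library. A pair may join sites of different genes. The edgeR quasi-likelihood test then took the reads at both sites of each library, with a term per library and the interaction of group and site as the tested term. The effect is the change of log2(distal/proximal) read ratio, positive for a shift to the distal site. For values per library, 0.5 was added to both counts.

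Differences of single measures between groups were tested with exact permutation tests, two-sided. In 3'READS they were run in R, with p as 2 times the smaller tail. For the mitochondrial share of RNA-seq counts, also in R, p was the share of splits with an absolute difference at least as large. The test of 3' UTR length and the search for 7-mers used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Each fit was tested on simulated data in which 200 genes, sites or pairs were changed. For RNA-seq, 67.2% of 1.5-fold, 77.6% of 2-fold and 81.8% of 3-fold changes were recovered for shRNA 1, and 58.2%, 73.1% and 87.9% for shRNA 2. For single sites, 7.46% of 2-fold, 56.7% of 4-fold and 83.3% of 8-fold changes were recovered for shRNA 1, and 0%, 56.7% and 81.8% for shRNA 2. For site pairs these were 1.49%, 32.8% and 54.5% for shRNA 1 and 0%, 20.9% and 51.5% for shRNA 2. In 3'READS the folds were raised to 2, 4 and 8 after an earlier simulation with at most 3-fold changes recovered 0. Changes of less than 4-fold at a site pair were thus mostly out of reach of these libraries.

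Alternatives tried were RLE size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block, fits with only the 2 groups compared, and each library left out in turn. For pairs they were also 50 reads in place of 20, 10% in place of 5%, the outermost sites of a run, Fisher's exact test on pooled reads and diffSpliceDGE. Added after seeing the data were runs joined within 1000 or 5000 nt, pairs at least 200 nt apart, fits without 3 libraries of 3'READS that stood apart, RNA-seq fits without shRNA 1 replicates 1 and 2 or 3 and 4, and the trend of pair shifts with spacing.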

Results

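Gene expression and poly(A) site use were measured in Kasumi-1 cells after knockdown of FIP1L1, a subunit of the cleavage and polyadenylation specificity factor that acts where pre-mRNAs are cut and tailed. RNA-seq covered 4 control, 4 shRNA 1 and 4 shRNA 2 libraries. Their totals were 14121476, 12236937, 15844043 and 19154704 counts for control replicates 1 to 4. They were 16703476, 20388437, 15782036 and 14019866 for shRNA 1, and 19208398, 17449209, 18317035 and 15418235 for shRNA 2. 3'READS covered 3 control libraries with 7519725, 10266407 and 7412062 counts, 4 shRNA 1 libraries with 5705530, 5666102, 9224785 and 8201000 counts, and 3 shRNA 2 libraries with 6781493, 10846661 and 9744829 counts. In RNA-seq the lowest correlation of log2 CPM within a group was 0.968 and the highest between groups 0.954, both across genes. No 2 libraries of a group agreed within sampling noise in either assay, since chi-square over degrees of freedom between replicates ran from 3.77 to 32.6 in RNA-seq and from 3.21 to 41.9 in 3'READS.

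The first question was how far FIP1L1 mRNA itself had been lowered. FIP1L1 (ENSG00000145216, GRCh38 chromosome 4, 53377643 to 53460861, plus strand) stood at 41.4 ± 2.27 CPM (SD, n = 4) in the control, 15.4 ± 1.55 CPM with shRNA 1 (n = 4) and 19.6 ± 0.788 CPM with shRNA 2 (n = 4). It fell by 1.43 on the log2 scale with shRNA 1 (SE 0.10, edgeR adjusted p = 1.92e-11), which left 37.1% of the control level. With shRNA 2 it fell by 1.08 (SE 0.10, edgeR adjusted p = 3.01e-09), which left 47.4%. Every library of both shRNAs lay below every control library. The level with shRNA 2 was higher than with shRNA 1 by 0.35 on the log2 scale (SE 0.10, edgeR adjusted p = 0.00415). LNX1 overlaps FIP1L1 on the other strand, and reads of the 2 genes cannot be told apart there.

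**Figure D1:**
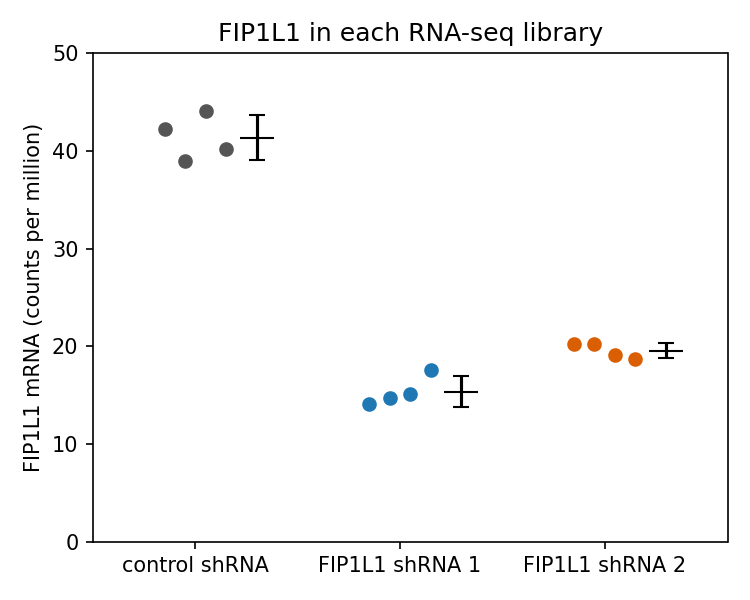
FIP1L1 mRNA in CPM (vertical axis) in each of the 12 RNA-seq libraries by group, 1 point per library, with the mean and SD of the 4 libraries as a bar beside them. The control libraries lie between 38.9 and 44.1 CPM and the libraries of both shRNAs between 14.1 and 20.2 CPM.

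The next comparison asked which genes changed with both shRNAs. AOC3, a vascular amine oxidase (GRCh38 chromosome 17, 42851184 to 42858130), rose from 4.12 ± 0.747 CPM (SD, n = 4) to 42.5 ± 9.66 with shRNA 1 and 34.5 ± 2.58 with shRNA 2, log2 changes of 3.39 (SE 0.16, edgeR adjusted p = 7.85e-14) and 3.08 (SE 0.16, 8.26e-13). HCST, the signalling adaptor DAP10 of natural killer receptors (GRCh38 chromosome 19, 35902480 to 35904377), rose by 3.00 and 3.84 on the log2 scale. LOX, the collagen cross-linking lysyl oxidase (GRCh38 chromosome 5, 122063195 to 122078360), fell from 53.2 ± 3.92 CPM to 4.87 ± 0.682 and 6.75 ± 1.67. MEF2C, a myeloid and muscle transcription factor (GRCh38 chromosome 5, 88717117 to 88904257), fell from 153 ± 2.80 CPM to 16.3 ± 2.65 and 37.6 ± 3.40, log2 changes of -3.23 (SE 0.10, edgeR adjusted p = 1.61e-17) and -2.02 (SE 0.09, 2.08e-14). MACROD2, an ADP-ribosylhydrolase (GRCh38 chromosome 20, 13995369 to 16053197), fell from 30.7 ± 5.30 CPM to 3.01 ± 0.723 and 3.37 ± 0.795.

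The other genes that the rule named as highest were WFIKKN1, LINC00304, CD82, CILP2, MASP2, RASSF2, ERV3-1 and P2RX2. Among them were the tetraspanin CD82, the Ras-association protein RASSF2 and the ATP-gated channel P2RX2. Over the 10 highest, log2 changes ran from 2.43 for P2RX2 to 3.82 for LINC00304 with shRNA 1, and from 2.48 for RASSF2 to 3.84 for HCST with shRNA 2. The other lowest genes were the receptor NOTCH3, the homeobox factor CUX2, the complement protease C1S, WFDC1, the orphan receptor GPR85, the cadherin CDH3 and the adhesion molecule CEACAM6. Over the 10 lowest, log2 changes ran from -4.26 for CUX2 to -2.07 for CEACAM6 with shRNA 1, and from -3.18 for MACROD2 to -2.02 for MEF2C with shRNA 2. The largest edgeR adjusted p among these 20 genes was 1.59e-07, for CD82 with shRNA 1. In 4 of them 1 library lay apart from the other 3 of its group, in the shRNA 2 group for CILP2 and in the control for RASSF2, ERV3-1 and NOTCH3.

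With shRNA 1, 4533 genes were higher and 4543 lower than in the control, 57.3% of the 15834 tested, and 1651 and 1313 of these moved at least 2-fold. With shRNA 2, 3911 were higher and 4001 lower, 50% of those tested, and 1106 and 1006 moved at least 2-fold. Both shRNAs raised 1989 genes and lowered 2033, while 1245 of the 5267 genes called with both went opposite ways. Independent lists of these sizes would share 1120 higher and 1148 lower genes and 2268 in opposite directions. Simulated unchanged groups with a shared simulated control had on average 0.05 higher and 0 lower genes called with both by edgeR. With nothing changed few genes are called at all, so this does not measure what shared controls add to real changes. With the controls split 2 and 2, 1396 higher and 1595 lower genes were shared, where independent lists gave 753 and 851.3, and 919.3 went opposite ways. Across genes, which are not independent replicates, the log2 changes of the 2 shRNAs correlated with r = 0.398 and rho = 0.383. Simulated unchanged groups gave r = 0.526 from the shared controls, and split controls gave 0.329. The covariance was 0.321 against 0.0453 in the simulation, a difference of 0.276. The median log2 change over all tested genes was 0.0203 with shRNA 1 and 0.000475 with shRNA 2.

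**Figure D2:**
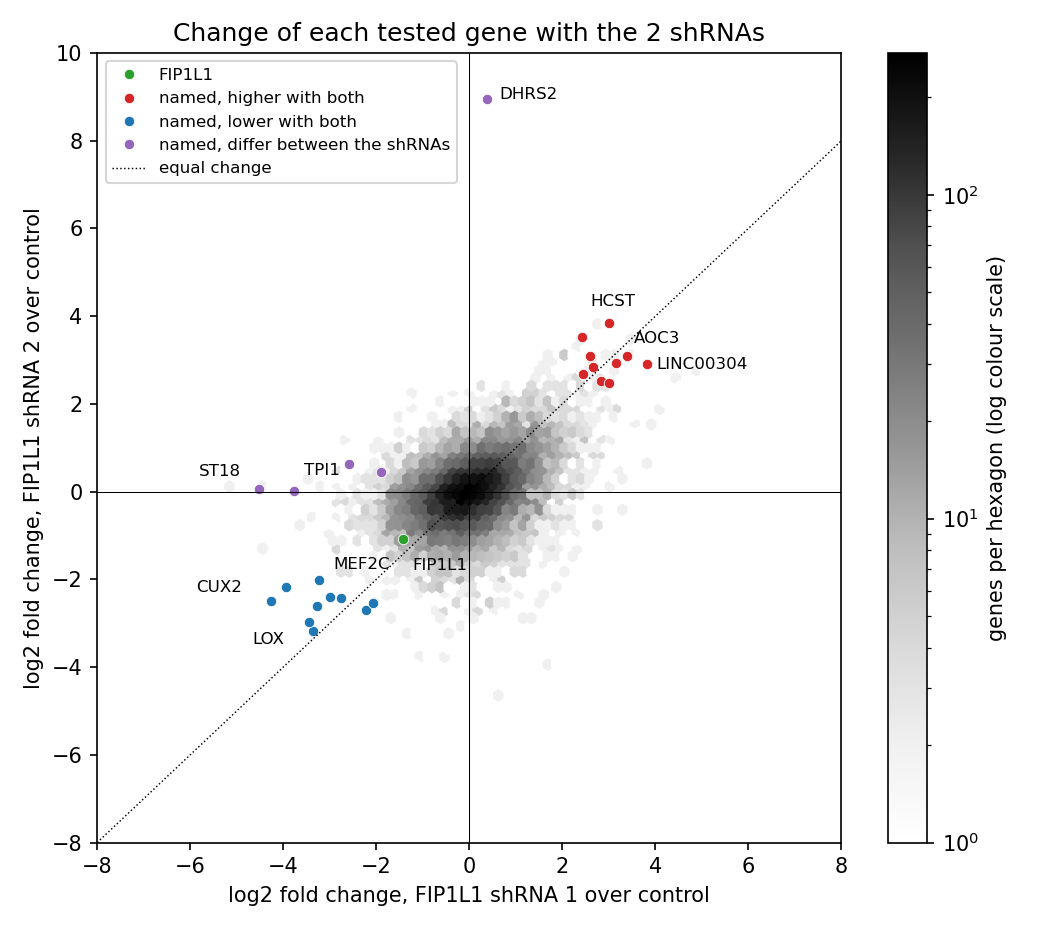
Log2 fold change over control of each tested gene with shRNA 1 (horizontal axis) and shRNA 2 (vertical axis), with the number of genes per hexagon on a log colour scale, named genes as coloured points and equal change as a dotted line. The 10 named highest and 10 named lowest genes lie far from 0 in the same direction with both shRNAs, while DHRS2 lies at 0.39 and 8.96 and TPI1 at -3.76 and 0.02, and 2 tested genes lie outside the plotted range.

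Among the factors that cut and tail mRNAs, transcripts of several partners of FIP1L1 were lower with both shRNAs. NUDT21, a subunit of cleavage factor I, fell from 196 ± 5.78 CPM (SD, n = 4) to 155 ± 9.92 with shRNA 1 and 101 ± 5.62 with shRNA 2, log2 changes of -0.34 (SE 0.06, edgeR adjusted p = 7.51e-05) and -0.97 (SE 0.06, 2.44e-11). CPSF2, a partner of the endonuclease, fell by 0.50 and 0.31 on the log2 scale (edgeR adjusted p = 1.86e-06 and 0.00082), and the scaffold SYMPK by 0.19 and 0.23 (edgeR adjusted p = 0.00807 and 0.0025). In SYMPK 1 shRNA 1 library lay below the other 3. The cleavage stimulation factor CSTF3 fell by 0.23 and 0.26 (edgeR adjusted p = 0.022 and 0.0156) and the poly(A) polymerase PAPOLA by 0.22 and 0.20 (edgeR adjusted p = 0.0115 and 0.0207). Of the 23 tested members, FIP1L1 included, 3 were higher, 14 lower and 6 not called with shRNA 1, and 6 were higher, 7 lower and 10 not called with shRNA 2. Of these, 18 and 15 were called when adjusted over the list alone. No member rose with both, 6 fell with both and 4 went opposite ways. As a list the machinery did not stand apart from other genes (camera adjusted p = 0.319 and 0.684). The call of CSTF3 was lost without control 2 (edgeR adjusted p = 0.0829 and 0.0653), control 4 (0.0691 and 0.055), shRNA 1 replicate 2 (0.0703 for shRNA 1) or shRNA 2 replicate 2 (0.067 for shRNA 2). That of PAPOLA was lost without shRNA 1 replicate 3 (0.0532 for shRNA 1), control 3 (0.0795 for shRNA 2), or shRNA 2 replicate 2 or 3 (0.053 and 0.0629 for shRNA 2).

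Markers of blood cell differentiation were examined next, since Kasumi-1 is a myeloid progenitor line. Transcripts of stem and progenitor cells were mostly lower. TAL1, a haematopoietic transcription factor, fell from 57.7 ± 2.90 CPM (SD, n = 4) to 16.4 ± 3.04 with shRNA 1 and 19.2 ± 0.725 with shRNA 2 (edgeR adjusted p = 2.14e-12 and 3.42e-11). The RNA-binding protein MSI2 fell by 0.76 and 0.98 on the log2 scale. HOXA9, at 0.404 ± 0.205 CPM in the control, rose by 2.32 and 2.25. Of the 23 tested genes of this list, 4 were higher, 15 lower and 4 not called with shRNA 1, and 3 were higher, 13 lower and 7 not called with shRNA 2, and 11 were lower with both. Adjusted over the list alone, 19 and 18 were called. Camera gave adjusted p = 3.33e-07 with shRNA 1, which held with an estimated correlation (adjusted p = 0.00438), and 0.0394 with shRNA 2, which was lost (adjusted p = 0.184 with an estimated correlation).

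More monocyte and macrophage transcripts were higher than lower. LYZ, lysozyme, rose from 0.639 ± 0.233 CPM (SD, n = 4) to 4.85 ± 1.96 with shRNA 1 and 6.41 ± 0.950 with shRNA 2, and the integrin ITGAM from 2.59 ± 1.08 to 6.39 ± 0.306 and 13.8 ± 1.17. CYBB, the oxidase subunit gp91phox, fell by 1.34 and 1.17 on the log2 scale. Of 17 tested genes, 9 were higher, 4 lower and 4 not called with shRNA 1, and 8 were higher, 2 lower and 7 not called with shRNA 2. There were 13 and 10 calls adjusted over the list alone. By camera the adjusted p was 0.204 with shRNA 1 and 0.0334 with shRNA 2, where it became adjusted p = 0.184 with an estimated correlation. Granulocyte transcripts went both ways. BPI, an antibacterial granule protein, rose by 2.71 and 0.84 on the log2 scale, and CEACAM6 fell by 2.07 and 2.53. Of 13 tested genes, 4 were higher, 5 lower and 4 not called with shRNA 1, and 1 was higher, 6 lower and 6 not called with shRNA 2 (camera adjusted p = 0.356 and 0.095), with 9 and 8 called when adjusted over the list alone.

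Lineages other than the myeloid one were covered by few detected markers. TFRC, the transferrin receptor, fell from 1055 ± 31.6 CPM (SD, n = 4) to 407 ± 11.3 with shRNA 1 and 719 ± 14.2 with shRNA 2. Among 6 tested erythroid and megakaryocyte genes, 2 were higher, 2 lower and 2 not called with shRNA 1, and 2 were lower and 4 not called with shRNA 2 (camera adjusted p = 0.441 and 0.314). Adjusted over that list alone, 4 and 2 were called, and with shRNA 1 its median of 0.27 and mean of 0.09 were positive while camera gave the direction down. Among 6 tested lymphoid genes, 1 was higher, 4 lower and 1 not called with shRNA 1, and 1 was higher, 1 lower and 4 not called with shRNA 2 (camera adjusted p = 0.209 and 0.343), with 5 and 1 called when adjusted over the list alone. CD79A, a B cell receptor chain named here after its values were seen, fell by 1.62 with shRNA 1 and rose by 1.40 with shRNA 2. MHC class II transcripts, which present antigen on myeloid and B cells, also parted. Of 9 tested genes, 5 were lower and 4 not called with shRNA 1, and 6 were higher and 3 not called with shRNA 2 (camera adjusted p = 0.356 and 0.108). Adjusted over the list alone, 5 and 7 were called, and 4 genes went opposite ways.

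The cholesterol biosynthesis and glycolysis lists fell with both shRNAs. SQLE, the squalene epoxidase of cholesterol synthesis, fell from 161 ± 6.54 CPM (SD, n = 4) to 57.8 ± 3.08 with shRNA 1 and 74.2 ± 2.49 with shRNA 2 (edgeR adjusted p = 9.49e-15 and 1.84e-12). DHCR7, the last enzyme of that pathway, fell by 1.17 and 1.40 on the log2 scale. Of 23 tested cholesterol biosynthesis genes, 2 were higher, 20 lower and 1 not called with shRNA 1, and 21 were lower and 2 not called with shRNA 2, and 19 were lower with both. With each shRNA 22 were called when adjusted over the list alone. Camera gave adjusted p = 1.64e-07 with shRNA 1, which was lost (adjusted p = 0.0514 with an estimated correlation), and 3.79e-15 with shRNA 2, which held (adjusted p = 0.0174). In glycolysis, ALDOC, aldolase C, fell from 62.9 ± 6.05 CPM to 16.4 ± 2.13 and 18.6 ± 1.99, and PFKM, the muscle phosphofructokinase, rose by 0.94 and 1.61 from 1.86 ± 0.781 CPM. Of 21 tested genes, 1 was higher, 17 lower and 3 not called with shRNA 1, and 3 were higher, 13 lower and 5 not called with shRNA 2, with 18 and 16 called when adjusted over the list alone. The glycolysis list had camera adjusted p = 4.55e-18 with shRNA 1 and 0.0149 with shRNA 2, and both calls were lost (adjusted p = 0.0514 and 0.406 with an estimated correlation).

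Of transcripts linked to mTORC1, the kinase complex that couples nutrients to growth, more were lower than higher with both shRNAs. GBE1, the glycogen branching enzyme (GRCh38 chromosome 3, 81489699 to 81762161), fell from 318 ± 19.6 CPM (SD, n = 4) to 71.4 ± 5.45 with shRNA 1 and 82.0 ± 6.36 with shRNA 2, and BCAT1, a branched-chain aminotransferase, from 149 ± 3.33 to 44.2 ± 12.2 and 19.5 ± 1.60. SLA, a myeloid and lymphoid signalling adaptor, rose from 2.74 ± 0.527 CPM to 8.0 ± 1.17 and 21.4 ± 1.27, with 1 shRNA 2 library below the other 3. Of 173 tested genes on the mTORC1 signalling list, 33 were higher, 106 lower and 34 not called with shRNA 1, and 36 were higher, 81 lower and 56 not called with shRNA 2. Adjusted over the list alone, 142 and 118 were called, and 61 were lower with both. For mTORC1 signalling camera gave adjusted p = 3.2e-11 and 0.000176, and both calls were lost (adjusted p = 0.0514 and 0.255 with an estimated correlation). Of these 173 genes, 49 also stand on another of the lists. The components of the mTOR pathway went both ways, with DEPTOR, an inhibitor of mTOR, falling by 1.94 and 2.40 on the log2 scale and the translation repressor EIF4EBP2 rising by 0.80 and 0.98. In DEPTOR 1 shRNA 1 library lay above the other 3. Of 45 tested components, 16 were higher, 15 lower and 14 not called with shRNA 1, and 18 were higher, 11 lower and 16 not called with shRNA 2 (camera adjusted p = 0.882 and 0.333). Adjusted over the list alone, 32 and 29 were called, and with shRNA 1 the median of 0.03 and the mean of -0.003 differed in sign while camera gave the direction up.

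Amino acid stress genes of the ATF4 list were mixed with shRNA 1 and mostly lower with shRNA 2. SLC7A5, a leucine transporter subunit, fell from 376 ± 26.3 CPM (SD, n = 4) to 220 ± 15.5 and 221 ± 7.77. PSPH, of serine synthesis, fell by 1.35 and 0.72 on the log2 scale, and SESN2, a leucine sensor, rose by 0.88 and 1.06. Of 23 tested genes, 8 were higher, 10 lower and 5 not called with shRNA 1, and 4 were higher, 12 lower and 7 not called with shRNA 2, with 19 and 16 called when adjusted over the list alone. The list had camera adjusted p = 0.239 with shRNA 1 and 0.0394 with shRNA 2, where it became adjusted p = 0.255 with an estimated correlation. In nuclear oxidative phosphorylation, CYC1, cytochrome c1, fell from 295 ± 6.25 CPM to 76.7 ± 18.3 and 193 ± 6.71, CYCS, cytochrome c, fell by 0.82 and 0.75, and COX7C, of cytochrome oxidase, rose by 1.09 and 1.07. Of 40 tested genes, 2 were higher, 26 lower and 12 not called with shRNA 1, and 2 were higher, 16 lower and 22 not called with shRNA 2, with 30 and 18 called when adjusted over the list alone. Tested as a list, these genes had camera adjusted p = 0.000547 with shRNA 1, which became adjusted p = 0.41 with an estimated correlation, and 0.122 with shRNA 2.

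The protein-coding genes of mitochondrial DNA were lower with shRNA 1. MT-ND6, a complex I subunit named here after its values were seen, went from 1003 ± 105 CPM (SD, n = 4) to 540 ± 82.1 with shRNA 1 and 1305 ± 153 with shRNA 2. All 13 fell with shRNA 1, while with shRNA 2 MT-ND6 was higher and the other 12 were not called, with 13 and 1 called when adjusted over the list alone. Camera adjusted p was 3.84e-05 with shRNA 1, which became adjusted p = 0.323 with an estimated correlation, and 0.959 with shRNA 2, where the median of -0.05 and the mean of -0.03 lay below 0 while camera gave the direction up. Mitochondrial genes took 8.15 ± 0.25% of RNA-seq counts in the control, 5.86 ± 1.2% with shRNA 1 and 8.65 ± 0.53% with shRNA 2 (n = 4 each; exact permutation test against the control, two-sided p = 0.0286, the smallest possible, and 0.171). The shRNA 1 libraries differed among themselves, with 7.20% and 6.45% in replicates 1 and 2 and 4.92% and 4.86% in replicates 3 and 4. Replicates 3 and 4 also correlated best, at 0.988 across genes against 0.968 to 0.975 for the other pairs of that group. In fits chosen after seeing the data, 12 of the 13 genes fell without shRNA 1 replicates 1 and 2, and 11 without replicates 3 and 4. In 3'READS the mitochondrial chromosome took 10.6 ± 1.12% of reads in the control (n = 3), 7.88 ± 1.04% with shRNA 1 (n = 4) and 14.4 ± 0.511% with shRNA 2 (n = 3). The exact two-sided p against the control was 0.0571 and 0.1, the smallest these group sizes allow, so neither difference could pass 0.05.

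Cell cycle genes were mostly lower with shRNA 1, while with shRNA 2 more were higher than lower. GINS2, of the replicative helicase, fell from 36.2 ± 3.10 CPM (SD, n = 4) to 21.1 ± 3.04 and 21.0 ± 1.69, and MCM6, a subunit of the same helicase, by 0.50 and 0.46 on the log2 scale, whereas the mitotic kinase TTK rose by 0.33 and 0.37. Of 37 tested genes, 3 were higher, 28 lower and 6 not called with shRNA 1, and 18 were higher, 7 lower and 12 not called with shRNA 2. Adjusted over the list alone, 31 and 25 were called, and 12 went opposite ways. For the cell cycle list camera gave adjusted p = 5.03e-07 with shRNA 1, which became adjusted p = 0.148 with an estimated correlation, and 0.0958 with shRNA 2. Of 18 tested p53 targets, TP53INP1, a stress-response gene, rose by 1.64 and 1.28, with 1 control library below the other 3, and MDM2, the ubiquitin ligase of p53, fell from 67.8 ± 3.57 CPM to 22.3 ± 4.31 and 38.9 ± 2.58. On that list 6 were higher, 3 lower and 9 not called with shRNA 1, and 7 were higher, 3 lower and 8 not called with shRNA 2 (camera adjusted p = 0.56 and 0.175), with 8 and 11 called when adjusted over the list alone.

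Cytosolic ribosomal protein transcripts, which share reads with pseudogenes, were mostly not called with shRNA 1. RPL11 fell from 1030.0 ± 64.7 CPM (SD, n = 4) to 480 ± 33.1 and 657 ± 55.9, and RPS23 rose by 0.45 and 0.95 on the log2 scale. Of 55 tested genes, 13 were higher, 7 lower and 35 not called with shRNA 1, and 2 were higher, 27 lower and 26 not called with shRNA 2, with 18 and 31 called when adjusted over the list alone. Camera adjusted p was 0.517 with shRNA 1 and 0.0184 with shRNA 2, where it became adjusted p = 0.636 with an estimated correlation. With shRNA 1 the list depended on the libraries. Without replicates 1 and 2, 28 were higher and 5 lower (camera adjusted p = 0.0295, direction up), and without replicates 3 and 4, 8 were higher and 18 lower (camera adjusted p = 0.422, direction down). Of the replication-dependent histones, whose main transcripts carry no poly(A) tail and whose copies are nearly identical, 7 were tested. H2AC6 rose from 0.152 ± 0.123 CPM to 0.999 ± 0.370 and 2.19 ± 0.532. On that list 1 was higher, 1 lower and 5 not called with shRNA 1, and 4 were higher and 3 not called with shRNA 2, with 2 and 4 called when adjusted over the list alone. Camera adjusted p was 0.987 and 0.0423, the latter adjusted p = 0.35 with an estimated correlation and 0.0652 without shRNA 1 replicates 3 and 4. Without these 2 libraries 4 histone genes were lower with shRNA 1.

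Of the immediate early, NF-kB and interferon lists, the first alone passed camera. EGR1, an immediate early transcription factor, rose from 2.27 ± 0.307 CPM (SD, n = 4) to 6.12 ± 1.90 with shRNA 1 and 28.8 ± 6.60 with shRNA 2, NR4A2, a nuclear receptor, rose by 1.35 with each on the log2 scale, and FOSL1, of the AP-1 family, fell by 0.77 and 1.05. Of 16 tested immediate early genes, 10 were higher, 2 lower and 4 not called with shRNA 1, and 6 were higher, 2 lower and 8 not called with shRNA 2, with 12 and 8 called when adjusted over the list alone. Camera adjusted p was 0.0276 and 0.0461, and both calls were lost (adjusted p = 0.385 and 0.406 with an estimated correlation). Without shRNA 1 replicates 3 and 4 camera gave adjusted p = 0.125 and 0.0599. On the NF-kB and inflammatory list, the cytokine IL1B rose by 2.57 and 3.23 from 0.0961 ± 0.0935 CPM, and SOD2, the mitochondrial superoxide dismutase, fell by 0.38 and 0.74, with 1 shRNA 1 library above the other 3. Of its 15 tested genes, 8 were higher, 2 lower and 5 not called with shRNA 1, and 10 were higher, 1 lower and 4 not called with shRNA 2 (camera adjusted p = 0.082 and 0.1), with 11 called for each when adjusted over the list alone. Among 26 tested interferon-stimulated genes, IFI27 rose from 0.524 ± 0.296 CPM to 3.14 ± 0.737 and 2.52 ± 0.438, and EIF2AK2, the kinase PKR, fell by 0.80 and 0.47. On that list 9 were higher, 3 lower and 14 not called with shRNA 1, and 8 were higher, 2 lower and 16 not called with shRNA 2 (camera adjusted p = 0.362 and 0.175), with 11 and 10 called when adjusted over the list alone. With shRNA 1 its median of -0.04 lay below 0 while its mean of 0.17 and camera pointed up.

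**Figure D3:**
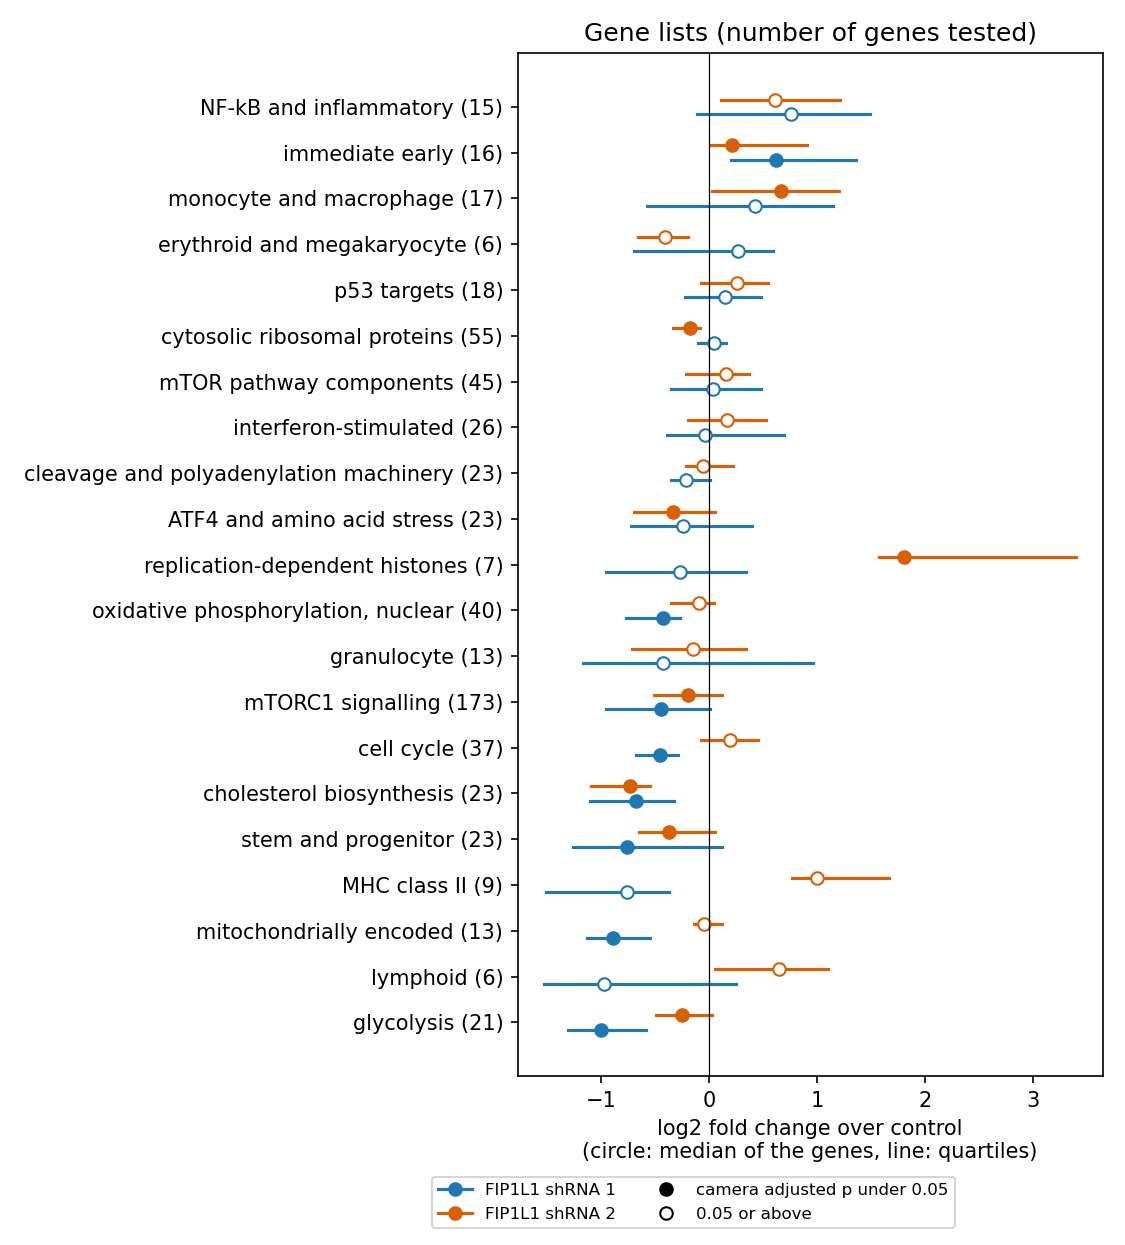
Log2 fold change over control of the tested genes of each of the 21 lists, with the median as a circle and the quartiles as a line for shRNA 1 and shRNA 2, filled circles for a camera adjusted p under 0.05, and the number of tested genes in parentheses. The glycolysis list has the lowest median with shRNA 1, the cholesterol biosynthesis list lies at -0.68 and -0.73, and the cell cycle list at -0.45 and 0.20.

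The 2 shRNAs were then set against each other. DHRS2, a mitochondrial dehydrogenase (GRCh38 chromosome 14, 23630115 to 23645639), stood at 0.312 ± 0.165 CPM (SD, n = 4) in the control, 0.397 ± 0.10 with shRNA 1 and 151 ± 7.47 with shRNA 2 (edgeR adjusted p between shRNAs = 2.55e-22). TPI1, triosephosphate isomerase of glycolysis (GRCh38 chromosome 12, 6867119 to 6870948), stood at 338 ± 32.1, 25 ± 3.99 and 344 ± 6.45 CPM, and ST18, a zinc finger factor (GRCh38 chromosome 8, 52110839 to 52460959), at 52.8 ± 4.60, 2.32 ± 0.181 and 54.9 ± 6.15 CPM (edgeR adjusted p = 3.22e-18 for both). IGFBP4, which binds insulin-like growth factors, fell by 2.58 on the log2 scale with shRNA 1 and rose by 0.63 with shRNA 2, and the annexin ANXA6 went from 418 ± 19.8 CPM to 113 ± 5.19 and 566 ± 30.5 CPM. Between the shRNAs 9299 genes differed, 58.7% of those tested, with 4643 higher and 4656 lower with shRNA 2. By list, shRNA 2 lay above shRNA 1 in 31 of 37 cell cycle genes and below in 2, with 4 not called (camera adjusted p = 1.66e-10), in 19 of 21 glycolysis genes and below in 1 (1.43e-09), and in 11 of 13 mitochondrially encoded genes (8.73e-05). It also lay above in 13 of 23 stem and progenitor genes and below in 4 (0.00404), in 88 of 173 mTORC1 signalling genes and below in 48 (0.00408), and in 8 of 9 MHC class II genes (0.0347). It lay below in 32 of 55 ribosomal protein genes and above in 2 (camera adjusted p = 0.00544). Adjusted over each list alone, 33 cell cycle, 20 glycolysis, 11 mitochondrially encoded, 17 stem and progenitor, 139 mTORC1 signalling, 8 MHC class II and 34 ribosomal protein genes differed. All 7 list calls were lost, with adjusted p = 0.103, 0.224, 0.494, 0.103, 0.494, 0.732 and 0.75 with an estimated correlation for the lists in that order. MHC class II was not called without shRNA 1 replicates 1 and 2 (camera adjusted p = 0.131) or 3 and 4 (0.152), nor were ribosomal proteins without 3 and 4 (0.198). Nuclear oxidative phosphorylation, not called with all libraries (camera adjusted p = 0.0543), was called without 3 and 4 (0.000324, higher with shRNA 2).

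Poly(A) site use was compared within pairs of neighbouring sites, given by hg19 position, to see whether transcripts ended earlier or later. On the minus strand of chromosome 9, the distal site at 137029600 took 3.39 ± 0.3% (SD, n = 3) of the reads of the pair with the site at 137029697 in the control, 54.3 ± 17.9% with shRNA 1 (n = 4) and 47.6 ± 11.9% with shRNA 2 (n = 3), log2 changes of 5.06 (SE 0.63, edgeR adjusted p = 0.00197) and 4.64 (SE 0.68, 0.00942). On chromosome 16, plus strand, the distal site at 71964538 rose from 10.5 ± 1.9% to 38.1 ± 4.97% and 32.6 ± 3.7% against the site at 71962908. On chromosome 22 the distal sites at 19833671 (minus strand, against 19837764) and 38365318 (plus strand, against 38363806) rose from 65.3% to 90.8% with each shRNA and from 3.52% to 12.7% and 17.8%. In the other direction, the distal site at 10399245 on the plus strand of chromosome 19 fell from 18.8 ± 4.84% to 2.26 ± 1.72% and 2.79 ± 1.72% against 10397290. The distal site at 93455033 on the plus strand of chromosome 11 fell from 98.9 ± 0.239% to 91.4 ± 1.68% and 52.6 ± 16.6% against 93454929, and this pair also differed between the shRNAs (edgeR adjusted p = 0.0022). Distal sites also lost reads on chromosome 14 (65541845 against 65541916), chromosome 11 (63391560 against 63391605), chromosome 1 (90285734 against 90285778) and chromosome 21 (46269513 against 46269576), all on the minus strand. Their control shares of 87.4%, 96.6%, 91.1% and 98.4% became 47.8%, 84.6%, 68.2% and 93.9% with shRNA 1 and 48.5%, 81.8%, 59.5% and 90.7% with shRNA 2. The genes at these sites were not assigned here.

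Of 5790 pairs with a median spacing of 511 nt and a median of 81 reads per library, 24 shifted to the distal and 20 to the proximal site with shRNA 1, and 10 and 20 with shRNA 2 (edgeR quasi-likelihood, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 721 and 557 pairs, where a share of 0.05 of the 5790 would pass with nothing changed. Both shRNAs shifted 4 pairs to distal and 7 to proximal, and no pair was called in opposite directions, where independent lists would share 0.041 and 0.069. In simulations of unchanged groups edgeR called no pair with both, an outcome set beforehand because nothing was changed. Between the shRNAs 29 pairs lay more distal and 35 more proximal with shRNA 2. Across pairs the changes of both shRNAs correlated with r = 0.431, against 0.54 in the simulation, and their covariance was 0.475 against 0.33, a difference of 0.144. Part of the shared calls may come from the shared controls, which are too few to split.

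In 3'READS 3 libraries stood apart from their groups. Control 3 correlated with controls 1 and 2 at 0.913 and 0.916, which correlated with each other at 0.967, all across sites. In shRNA 1, replicates 3 and 4 correlated at 0.961, and replicates 1 and 2 with the others and each other at 0.842 to 0.877. Without these 3 libraries, a fit chosen after seeing the data, 250 pairs shifted to distal and 209 to proximal with shRNA 1, 324 and 362 with shRNA 2, and 90 and 95 with both. These held all 4 and all 7 pairs called above. The fit keeps controls 1 and 2, shRNA 1 replicates 3 and 4 and all of shRNA 2. Taking out libraries that differ from their group lowers the spread, and the rest are the same libraries. The repeated calls are therefore no separate support. With any 1 library left out the counts ran from 5 to 34 and 3 to 26 for shRNA 1, 0 to 24 and 1 to 33 for shRNA 2, and 0 to 6 and 1 to 9 for both. For shRNA 1, to distal and to proximal, they were 8 and 6 without control 1, 5 and 3 without control 2, 14 to distal without shRNA 1 replicate 3, and 13 and 11 without any of the shRNA 2 replicates. For shRNA 2 they were 3 and 4 without control 1, 0 and 1 without control 2, 13 to proximal without control 3, 24 and 33 without shRNA 1 replicate 1, 0 and 1 without shRNA 2 replicate 1 or 2, and 2 and 4 without shRNA 2 replicate 3. For both they were 1 and 1 without control 1, 0 and 1 without control 2, 2 to distal without control 3, 3 to proximal without shRNA 1 replicate 3, 0 and 1 without shRNA 2 replicate 1 or 2, and 1 and 1 without shRNA 2 replicate 3. Without control 2, shRNA 2 replicate 1 or shRNA 2 replicate 2, edgeR called 0 pairs to distal with shRNA 2. In these fits 236, 178 and 173 pairs had an unadjusted p under 0.05 in that direction. Some pass by chance, since with nothing changed a share of 0.05 of the 5790 pairs would do so over both directions. Over all libraries, unlike these fits, diffSpliceDGE called 20 and Fisher's exact test on pooled reads 1054. Fisher's test ignores the spread between libraries, so its count is no evidence of shifts that edgeR missed.

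Single poly(A) sites were tested as a measure of how much RNA ended at each. Of 28075 sites, 2419 held more and 2349 fewer reads with shRNA 1, and 1085 and 1248 with shRNA 2 (edgeR quasi-likelihood, Benjamini-Hochberg), of which 2220, 1947, 1040 and 1110 moved at least 2-fold. Both shRNAs raised 415 sites and lowered 424, and 72 went opposite ways, where independent lists would share 93 and 104. In simulations of unchanged groups edgeR called no site with both, an outcome set beforehand because nothing was changed. Between the shRNAs 2816 sites were higher and 3334 lower with shRNA 2. Across sites the changes correlated with r = 0.395, against 0.544 in the simulation, and the covariance was 0.552 against 0.187, a difference of 0.365. Without the 3 libraries that stood apart, 4673 and 4784 sites were called with shRNA 1 and 4819 and 4996 with shRNA 2. For shRNA 1 the counts were 1238 higher and 1448 lower without control 1, and 1264 and 1404 without control 2. For shRNA 2 they were 452 and 697 without control 1, 470 and 670 without control 2, and 399 and 375, 395 and 353, and 442 and 388 without shRNA 2 replicates 1, 2 and 3. They were 1812 and 1979 without shRNA 1 replicate 1, and 1728 were higher without shRNA 1 replicate 2.

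The shift of a pair went with the distance between its 2 sites, a pattern noticed in the data and tested afterwards. Pairs were ranked by spacing and parted into 3 groups of about equal size. In the widest group (1930 pairs, 947 to 7355 nt apart) the median log2 change of the distal over proximal ratio was 0.22 with shRNA 1 and 0.14 with shRNA 2. In the closest group (1931 pairs, 25 to 230 nt) it was -0.09 and -0.20, and in the middle group (1929 pairs, 231 to 945 nt) 0.09 and 0.03. Of the pairs called, the widest group held 16 to distal and 6 to proximal with shRNA 1 and 7 and 5 with shRNA 2, and the closest group 3 and 11, and 2 and 15. Within each library, the rank correlation across pairs between spacing and the distal over proximal ratio, relative to the mean of all libraries, ran from -0.12 to -0.101 in the controls, 0.0249 to 0.0464 with shRNA 1 and 0.0494 to 0.0905 with shRNA 2. The 7 libraries of both shRNAs lay above the 3 controls by 0.158 (exact permutation test, two-sided p = 0.0167, the smallest it can give). For shRNA 1 alone the difference was 0.145 (exact p = 0.0571) and for shRNA 2 alone 0.176 (exact p = 0.1), again the smallest these group sizes allow. Without the 3 libraries that stood apart it was 0.199 (exact p = 0.0952). Left out in turn, control 1, 2 or 3 gave differences of 0.148, 0.155 and 0.166 (exact p = 0.0556 each, the smallest that 7 libraries against 2 allow), and with pairs at least 200 nt apart it was 0.0845 (exact p = 0.0167).

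**Figure D4:**
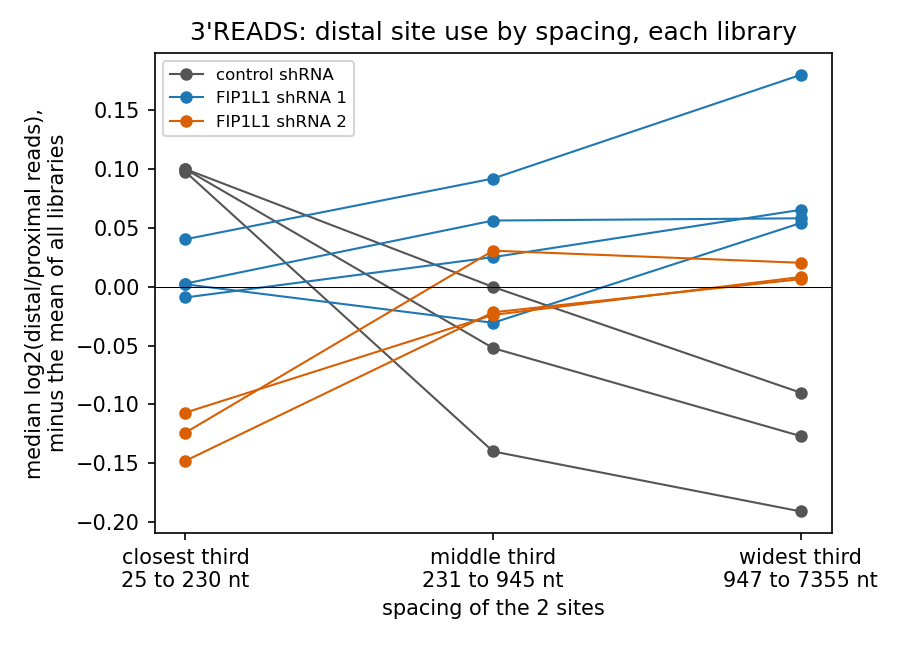
Median log2 ratio of distal over proximal reads, minus the mean of all libraries (vertical axis), in the closest, middle and widest of 3 groups of site pairs by spacing in nt (horizontal axis), with 1 line per 3'READS library. The 3 control libraries lie highest of all in the closest group (0.0976 to 0.0999) and lowest in the widest (-0.191 to -0.0901).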

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

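The tests of the degree of knockdown, of pairs with few reads, of the 3 libraries that stand apart, of shallow sequencing and of exchanged labels were chosen only after the result was seen.

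The RNA-seq response to the 2 shRNAs differed in 9299 genes, and 1245 genes were called with both but in opposite directions. A different degree of FIP1L1 knockdown alone would scale the changes, so the 23.6% of genes called with both that went opposite ways argue against it as the whole cause. The guide strand of an shRNA may also lower other mRNAs that match its seed in their 3' UTR. Among 7-mers of FIP1L1 transcripts a different one stood out for each shRNA (z = -8.12 for shRNA 1 and -7.42 for shRNA 2). The lowest z in 1 shuffle of the shRNA 1 effects over genes was -3.61. In the real effects, 7-mers not found in FIP1L1 transcripts reached -6.46 with shRNA 1 (GGACTAG) and -4.94 with shRNA 2 (GGTACCA). GGACTAG shares the run GGACTA with GGGACTA, the leading 7-mer of shRNA 1, so its value is not a separate background for it. Matches to the leading 7-mer of each shRNA could account for a small part of the difference, since both together went with 0.837% of its variance. Of their carriers, 69.8% differed between the shRNAs against 64.3% of other genes. Most of the difference stays open, including a response to FIP1L1 loss that changes direction with its degree, which was not tested.

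Distal site use rose with the spacing of a site pair under both shRNAs relative to the control, by 0.158 in rank correlation. After all libraries were thinned to the same depth the difference was 0.156, with at least 50 reads per pair it was 0.192, and without the 3 libraries that stand apart it was 0.199, which argues against depth, few reads and those libraries as the cause. Close pairs carry part of it, because with pairs at least 200 nt apart it was 0.0845. A candidate explanation is that loss of FIP1L1 shifts 3' ends toward later sites where sites lie far apart. It remains a hypothesis found and tested on the same libraries, pairs could not be tied to genes here, and priming at internal A-rich stretches or a preparation shared by the 3 controls was not tested.

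In 3'READS control 3 and shRNA 1 replicates 1 and 2 stood apart from their groups, and the deviations of control 3 and shRNA 1 replicate 1 from their group means correlated at 0.417. After thinning to equal depth control 1 still correlated with control 3 at 0.916, against 0.963 with control 2, which argues against shallow sequencing. Had control 3 and shRNA 1 replicate 1 carried each other's label, control 3 would follow the shRNA 1 effect, but its slope on that effect was 0.0681, while shRNA 1 replicates 1 and 2 had slopes of 0.839 and 0.866. A shared preparation may be behind control 3 and shRNA 1 replicate 1, but the labels give no batch. Within shRNA 1, replicates 1 and 2 correlated with each other at 0.842. That was below their correlations with replicates 3 and 4, at 0.871 and 0.863 for replicate 1 and 0.877 and 0.867 for replicate 2. These values give no sign of a preparation common to replicates 1 and 2. A link of replicate 2 to control 3 was not tested. No biological explanation was tested.

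Chance alone would set 1 library of 4 this far from the others in about 1 of 20 groups, and 11 of 258 groups examined, over named genes and library measures, had such a library. The highest shRNA 2 library of CILP2 stood at 37.7 CPM, the highest control libraries of RASSF2 and CXCR4 at 6.8 and 1.28 CPM, the lowest control libraries of ERV3-1, NOTCH3 and TP53INP1 at 0.622, 11.7 and 2.63 CPM, and the lowest shRNA 1 library of SYMPK at 173 CPM. The lowest shRNA 2 library of SLA stood at 19.5 CPM, the highest shRNA 1 libraries of DEPTOR and SOD2 at 37.2 and 122 CPM, and the highest shRNA 2 library of DUSP2 at 21.5 CPM.

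The shRNAs differed by camera in the lists cell cycle (adjusted p = 1.66e-10), glycolysis (1.43e-09), mitochondrially encoded (8.73e-05), stem and progenitor (0.00404), mTORC1 signalling (0.00408), cytosolic ribosomal proteins (0.00544) and MHC class II (0.0347). With an estimated correlation all 7 calls were lost (adjusted p from 0.103 to 0.75). Reads on the mitochondrial chromosome, which the site tests leave out, made up 14.4% of 3'READS reads with shRNA 2 against 10.6% in the control.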

How the results depend on the processing

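Runs joined within 1000 or 5000 nt, pairs at least 200 nt apart, and fits without 3 libraries of 3'READS or 2 of RNA-seq were chosen only after the result was seen, and the spacing trend was itself added after seeing the data. No called named gene changed direction with RLE scaling, the replicate number as a block or 1 library left out. No list called against the control changed direction under an alternative. For all called genes, direction was followed only without shRNA 1 replicates 1 and 2 or 3 and 4, with no opposite call. Among values not called, TPI1 with shRNA 2 ran from -0.025 to 0.0795 on the log2 scale, without control 2 and control 3, and by fry, unlike camera, mTOR pathway components with shRNA 1 (adjusted p = 0.142) and mitochondrially encoded genes with shRNA 2 (0.957) pointed down. Camera turned for that last list without shRNA 1 replicates 1 and 2 (adjusted p = 0.939) or 3 and 4 (0.982), for histones with shRNA 1 without replicates 1 and 2 (0.595), and for ribosomal proteins with shRNA 1 without 3 and 4 (0.422). The granulocyte list with shRNA 2 was called without replicates 1 and 2 (0.0364). The RNA-seq counts stayed within 1.5 times with RLE scaling, no filter, DESeq2, only the 2 groups compared, the replicate number as a block and each library left out. Without shRNA 1 replicates 1 and 2 both shRNAs raised 2224 and lowered 2395 genes, and without replicates 3 and 4 they raised 1920 and lowered 2021. With 1 library left out the counts ran from 4297 to 4589 higher and 4315 to 4636 lower for shRNA 1, 3492 to 4195 and 3675 to 4239 for shRNA 2, 1752 to 2101 and 1834 to 2222 for both, and 8665 to 9468 between the shRNAs. The correlation of both shRNAs was 0.404 at a mean of at least 10 CPM. Of the 83 named genes, 10 lost a call with 1 library left out, CSTF3, PAPOLA, IRF9, CCNE2, OLFM4, CD79B, CXCR4, PFKFB4, AEN and RPS19, and none with RLE scaling or the block. Beyond CSTF3 and PAPOLA the largest edgeR adjusted p was 0.154 for IRF9 with shRNA 1 (without control 4), 0.152 for CD79B with shRNA 2 (without control 3) and 0.125 for OLFM4 with shRNA 2 (without shRNA 2 replicate 4). Of the list calls, 8 for shRNA 1 and 9 for shRNA 2, 1 and 1 were kept with an estimated correlation, and fry, which does not compare a list with other genes, called 17 and 20.

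Counts of single sites and pairs moved with many settings, and the cause was not tested unless the setting itself gives it. For sites, higher and lower, no filter on low counts gave 805 and 1033 for shRNA 1 and 446 and 282 for shRNA 2, by testing 1608780 sites. DESeq2 called 1924 higher with shRNA 2, and leaving out the 3 libraries gave 4673 and 4784, and 4819 and 4996. With 1 library left out the counts ran from 1238 to 2632 and 1404 to 2664 for shRNA 1, and from 395 to 1812 and 353 to 1979 for shRNA 2. For pairs, to distal and to proximal, runs joined within 1000 nt gave 9 and 16 with shRNA 1, 4 and 15 with shRNA 2 and 1 and 5 with both. Runs within 5000 nt gave 67 and 37, 29 and 25, and 7 and 9. Pairs at least 200 nt apart, which leave out the close pairs, gave 24 and 10, 8 and 4, and 3 and 0 by edgeR. Against 24 and 20, 10 and 20, and 4 and 7 in all pairs, which direction held more pairs depended on the setting, as it did for sites. Among pairs at least 200 nt apart, 217 with shRNA 1 and 153 with shRNA 2 had an unadjusted p under 0.05 toward proximal. With nothing changed, a share of 0.05 of the 4451 pairs would pass over both directions together. Fisher's exact test on pooled reads, which ignores the spread between libraries, gave 1261 and 970, 1054 and 1083, and 476 and 371 with both. DiffSpliceDGE gave 54 and 38 with shRNA 1 and 20 and 31 with shRNA 2. Fits of only the 2 groups compared gave 8 and 10 for shRNA 1 and 64 and 81 for shRNA 2, and leaving out the 3 libraries 250 and 209, 324 and 362, and 90 and 95. With 1 library left out, pairs ran from 5 to 34 and 3 to 26 for shRNA 1, 0 to 24 and 1 to 33 for shRNA 2, and 0 to 6 and 1 to 9 for both. The spacing trend was 0.199 without the 3 libraries (exact p = 0.0952, the smallest possible) and ran from 0.148 to 0.17 with 1 library left out.

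Replicate numbers did not pair the samples. Deviations of libraries with the same number correlated from -0.0369 to 0.0893 over 12 pairs of RNA-seq libraries and from -0.351 to 0.0927 over 9 pairs in 3'READS, and 4 of 12 and 1 of 10 libraries correlated best with their own number. With the replicate number as a block, edgeR called 4508 and 4615 genes with shRNA 1, 3977 and 4028 with shRNA 2, 2002 and 2076 with both and 9337 between them. The same block gave lists 8 and 10, adding MHC class II with shRNA 2 (camera adjusted p = 0.011), and between the shRNAs added nuclear oxidative phosphorylation (0.0162) and lymphoid (0.0417). It gave sites 1380 and 1390 with shRNA 1 and 485 and 502 with shRNA 2, and pairs 1 and 1 with shRNA 1, 0 and 1 with shRNA 2, and 0 and 0 with both. Under the block 379 and 283 pairs with shRNA 1 and 210 and 197 with shRNA 2 had an unadjusted p under 0.05. With nothing changed, a share of 0.05 of the 5790 pairs would pass for each shRNA. DiffSpliceDGE without the block called 5 and 10 with both. Alternatives for intronic sites, gene totals and the correlation of the assays were not run, since sites were not assigned to genes. Simulated 2-fold changes of pairs were recovered in 1.49% for shRNA 1 and 0% for shRNA 2, and asking for at least 50 reads gave 28 and 23 pairs, and 13 and 22.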

Other observations

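The shares and numbers of genes that carry a 7-mer, the place of the 7-mers in FIP1L1 and the values of single mitochondrial sites were computed only after the result was seen.

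Sites on the mitochondrial chromosome also differed in 3'READS, as values without a test. The site at position 9991 of the plus strand (hg19) took 3.39 ± 0.316% of all reads (SD, n = 3) in the control, 1.57 ± 0.369% with shRNA 1 (n = 4) and 3.54 ± 0.173% with shRNA 2 (n = 3). The site at 219 of the minus strand took 2.16 ± 0.27%, 1.12 ± 0.253% and 2.61 ± 0.0892%, and the site at 3043 of the plus strand 0.119 ± 0.0372%, 0.328 ± 0.0556% and 0.151 ± 0.033%. Other plus-strand sites stood highest with shRNA 2, at 1.51 ± 0.486%, 1.2 ± 0.388% and 2.41 ± 0.204% for 12138, 0.515 ± 0.212%, 0.242 ± 0.121% and 0.959 ± 0.0885% for 9206, and 0.0896 ± 0.0161%, 0.055 ± 0.0213% and 0.19 ± 0.0331% for 10405.

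The hypothesis that each shRNA also acts on other mRNAs through its seed was tested with a prediction written before its result was seen. It was that the 7-mer whose 3' UTR carriers were lowest would lie in a FIP1L1 transcript, with z below -6. That 7-mer should also not stand apart under the other shRNA. The shRNA sequences are not given in the sources used here, so all 7-mers were searched, 4272 of which occur in FIP1L1 transcripts. The search covered 11675 genes, 83.2% of the 14030 tested genes with a mean of at least 1 CPM. Over all 7-mers, the leading one of each shRNA lay in FIP1L1 transcripts. For shRNA 1 the leading 7-mer was GGGACTA, with z = -8.12 (-1.65 for shRNA 2) and a mean log2 difference of -0.18 over 1238 carriers. For shRNA 2 it was GTAGATA, with z = -7.42 (0.171 for shRNA 1) and -0.16 over 973 carriers. In FIP1L1 itself the longer matches are GGGACTAT at GRCh38 chromosome 4, 53452986 to 53452993, in a coding exon of 4 of the 8 transcripts that hold it, and GTAGATAC at 53459487 to 53459494, in an exon and mostly in the UTR, in 7 of 13 transcripts. Of all possible 7-mers 26.1% occur in FIP1L1 transcripts, so a leading 7-mer could fall there by chance.

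Of 79 named genes with a searched 3' UTR, 20 carry either 7-mer. Among the 10 lowest with both shRNAs 6 do, NOTCH3 and CDH3 the shRNA 1 one and LOX, C1S, GPR85 and MEF2C the shRNA 2 one. The 7-mers were picked for the low values of their carriers in these same libraries, so that count is no separate evidence of a seed effect. All 10 lowest fell with both shRNAs, so a match to 1 of the 7-mers would account for at most 1 of the 2 falls. Of the 5 genes with the smallest adjusted p between the shRNAs, TPI1 carries the shRNA 1 7-mer, and ST18 carries the shRNA 2 one but fell with shRNA 1 alone (log2 change -4.51, against 0.05 with shRNA 2), while DHRS2, IGFBP4 and ANXA6 carry neither. Of the 5 cleavage and polyadenylation genes named with FIP1L1, CPSF2 and PAPOLA carry the shRNA 1 7-mer and NUDT21 the shRNA 2 one (log2 change -0.34 with shRNA 1 and -0.97 with shRNA 2), so a part played by seed matches in these falls stays open. Among the 9677 searched genes with neither 7-mer, the effects of both shRNAs correlated at 0.425. Among carriers of the shRNA 1 7-mer 44.7% were lower with shRNA 1, against 33.8% of other genes. For the shRNA 2 7-mer and shRNA 2 these were 43.9% and 27.8%, again in the libraries that picked the 7-mers. Carriers of either made up 18.3% of the searched genes that differed between the shRNAs, near their share of all searched genes, since 9677 of 11675 carried neither. Matches to these 2 7-mers (z = -8.12 and -7.42) may add to single genes but leave most differences unaccounted for, and other seed matches were not counted.

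The hypothesis that knockdown changes the levels of mRNAs with long 3' UTRs relative to short ones, in the same way with both shRNAs, was tested over 11675 genes. Within each library, 3' UTR length was rank-correlated with the log2 CPM of a gene minus its mean over all libraries. This relative correlation lay at 0.0431 ± 0.0341 (SD, n = 4) in the control, -0.0246 ± 0.135 with shRNA 1 (0.125 and 0.0444 in replicates 1 and 2, -0.0881 and -0.179 in replicates 3 and 4) and -0.0298 ± 0.0374 with shRNA 2. Neither difference passed an exact two-sided permutation test (-0.0677, p = 0.4, and -0.073, p = 0.0571), so the hypothesis was not borne out.

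Other splits of the same libraries into groups of the same sizes were fitted for each count. In RNA-seq only the real split, 1 of 35, reached the real count. This held for shRNA 1 (9076 genes, 0 in the highest other), shRNA 2 (7912 and 0) and shRNA 2 against shRNA 1 (9299 and 0). That share is under 0.05 and the smallest that 35 splits allow, so it argues against chance without excluding it. Each other split mixes libraries of both groups on both sides, which can widen the fitted spread and lower its count. At an unadjusted p under 0.05 those highest other splits held 2744, 1570 and 2577 genes. Genes called with both shRNAs in the same direction reached the real 4022 in 2 of 60 groupings drawn, the real one included. This share is under 0.05. The other was 4728, from a grouping that takes the 4 shRNA 1 libraries as the control and so follows the structure of the samples. There both shRNA groups mixed control and shRNA 2 libraries, so a shared control that stands apart can give an overlap this large. The test thus does not exclude that source for the 4022. For the number of gene lists called, 13 of 35 splits reached the 8 lists of shRNA 1 (highest other 10) and 4 of 35 the 9 lists of shRNA 2 (highest other 11), so chance cannot be excluded for these numbers. In 3'READS the 4768 sites called with shRNA 1 were reached by 1 of 35 splits, the real one. The highest other, 1519, takes control 3 and shRNA 1 replicates 1 and 2 as the control. This is again the smallest share possible, so it argues against chance without excluding it. The 44 pairs called with shRNA 1 were reached by 2 of 35 splits, so chance is not excluded. The 11 pairs called with both shRNAs were reached by 2 of 60 groupings drawn, the real one included, a share under 0.05. The other gave 277, so a grouping other than by shRNA gave more such pairs. The test therefore does not exclude chance or the structure of the libraries as their source. The highest others, 613 and 277, each take control 3 and shRNA 1 replicates 1 and 2 as the control and point to the structure of the samples. For shRNA 2 in 3'READS the 10 splits are too few for a share under 0.05, with 2333 sites (highest other 0) and 30 pairs (highest other 0) in the real split, which was 1 of 10 in both, while 770 sites and 132 pairs of the highest other had an unadjusted p under 0.05.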
